A study of Rattus norvegicus with 8 samples.

How the data were processed

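Total RNA from 8 samples of the rat thyroid line FRTL-5 (sub-clone SB5) was extracted with Trizol and columns, turned into biotin-labelled cRNA and hybridised to single-colour Affymetrix rat arrays, per the labels' protocols. The labels give 4 groups of 2 arrays, from cells with the wild type or the L629F human TSH receptor and with 1 mM sodium iodide or 1 mM sodium chloride. All cells were grown with 5 mU/ml bovine TSH. The deposited values were intensities on a linear scale, 1 per probe set and array, made with MAS5, per the submitters' processing notes. Its version, scaling target and use of detection calls are not given in the sources used here. Across 31099 probe sets, the mean of each array without the lowest and highest 2% was 500.2, so the arrays had been brought to a common level before deposit. No scanner files were used here.

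Gene symbols came from the platform annotation paired with the deposited probe sets, and 20764 of them were matched to a current entry of the GRCr8 gene table, which served only for names and for the order of genes. Of the probe sets, 20832 had 1 symbol (14218 genes), 436 had several and 9831 had none; no gene was named from the latter. The 57 control probe sets and the lowest 40% by mean log2 signal (mean signal under 69.9) were left out. Of the 18631 probe sets kept, 4704 had no symbol or several and stayed out of the main fit, and of the rest the brightest probe set stood for each gene, which left 10047 genes, 2838 of them with several kept probe sets. Values were log2(signal + 35.3), the pseudocount being the 25th percentile of all signals; this scale understates the change of dim genes. The design called for centring if the arrays' medians lay over 0.25 log2 apart without saying over which probe sets. They spanned 0.06 over the kept probe sets and 0.253 over all, so read over all probe sets the rule called for centring. The main fit followed the kept probe sets and was not centred, and centring by either median was run as an alternative. The choice matters for the receptor comparison. Without iodide it had 34 genes higher and 15 lower, and 18 and 73 when centred on all probe sets.

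Each gene was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) with a coefficient for each of the 4 groups, so that all comparisons shared 1 estimate of the spread (4 residual degrees of freedom, 9.52 prior). The 6 comparisons were iodide against chloride in each line, the average of these, their difference (interaction), and L629F against wild type without and with iodide. The tests were two-sided with Benjamini-Hochberg adjustment over all genes at 0.05. Of 29 gene lists, the 26 with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. The same lists were tested with an estimated correlation and with fry. Among the lists were markers of leucocytes (5 tested members), C cells (3), fibroblasts (2) and endothelium (3), and the last 3 of these had too few members to be tested. Tables were read with the package data.table (version 1.17.8), and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

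The genes named are the 10 with the largest rise and the 10 with the largest fall per comparison among those past the threshold whose groups did not overlap (for the average, whose mean moved the same way in each line), filled up with the 5 of smallest p in a direction with fewer. To these come thyroid genes fixed in advance, whatever their p, and up to 4 members of each list described, by smallest p. Further list members past the threshold were named after their values had been seen. Slc26a4 and Iyd were too dim to be tested.

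The fit was tested on simulated data with the real genes' means and spread. Over 20 runs of 10047 genes, the comparison in wild type cells recovered 17.6% of changes of 0.5 log2, 74.0% of 1 and 95.3% of 2, with 6.27% false calls. For the average over both lines the shares were 48.3%, 91.0% and 99.4%, with 5.89% false calls. The simulated noise was independent between genes and held no differences shared by a whole array. These shares are therefore not the false-call rate of the real arrays. The number of arrays limits the precision, and a median SE was 0.20 log2 for a comparison within a line and 0.14 for the average. The alternatives changed the pseudocount, the dim-probe filter, the scaling, the choice of probe set, the variance moderation, the arrays in the fit, the replicate term and the threshold, and left out each array in turn.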

Results

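FRTL-5 is a line of rat thyroid follicular cells whose growth and function depend on thyrotropin (TSH). The cells stably expressed the human TSH receptor, either wild type or with L629F, a substitution that activates the receptor without hormone. Each line received 1 mM sodium iodide or, as a control of equal salt strength, 1 mM sodium chloride, and each of the 4 groups was measured on 2 arrays. The series asked which transcripts change with iodide in a cell model of thyroid autonomy, the state in which thyroid tissue works without control by TSH. Median signals ran from 118 to 127 on the wild type arrays and from 138 to 147 on the L629F arrays. The 25th percentiles ran from 29.3 to 31.6 and from 40.8 to 43.1. Low signals were thus higher on every L629F array, which bears on dim genes in the comparison of receptors. The log2 signals of the 2 arrays of a group correlated at 0.971 to 0.981 across genes, against 0.954 for the least similar pair of arrays. The GAPDH 3′ to 5′ signal ratio, which is higher where RNA is degraded, averaged 2.32 ± 0.716 on iodide and 1.62 ± 0.397 on control arrays (SD, n = 4 each; exact two-sided permutation p = 0.171), with the highest value on wild type iodide replicate 2 (3.13). The beta-actin 3′ to 5′ ratio was 2.23 and 5.05 on the wild type control arrays and 3.66 and 9.15 on the wild type iodide arrays. In L629F cells it was 5.93 and 7.90 without and 5.95 and 6.48 with iodide. Both L629F control arrays thus lay above both wild type control arrays. The labels give 1 line per receptor and no duration of treatment. They do not say that the replicates are separate cultures, so p-values measure only the spread between these samples, which can be technical.

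Averaged over both lines, genes of fatty acid and cholesterol synthesis were lower in cells given iodide. Thrsp, a nuclear regulator of lipogenic genes, fell from a signal of 2704 ± 126 to 846 ± 161 in wild type cells and from 4489 ± 126 to 1892 ± 124 in L629F cells (SD, n = 2 arrays per group), a mean log2 change of -1.44 ± 0.11 (SE, adjusted p = 4.53e-05). Scd, the desaturase that makes monounsaturated fatty acids, changed by -1.62 ± 0.16 (adjusted p = 0.000353), the fatty acid elongase Elovl6 by -0.91 ± 0.13 (adjusted p = 0.00406) and Acsl1, which activates long-chain fatty acids, by -0.59 ± 0.10 (adjusted p = 0.00824). Of the 16 measured genes of the fatty acid synthesis list, 9 fell and none rose. The others that fell were Srebf1, Fasn, Acly, Acsl3 and Acaca. With the p-values adjusted over the list alone 12 fell, and all 16 had a negative mean change. Of 8 fits that each left out 1 array, Srebf1 passed in 7, Acsl1 in 6, Fasn in 5, Acly and Acaca in 4 and Acsl3 in 2 (adjusted p up to 0.142). The list as a set was lower (camera, adjusted p = 4.86e-17, and adjusted p = 0.0184 with an estimated correlation).

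Of the 20 measured genes of cholesterol synthesis, 4 fell. These were Fdps, which makes farnesyl diphosphate (-0.53 ± 0.09, adjusted p = 0.00743), and Acat2, an acetyl-CoA acetyltransferase (-0.62 ± 0.11, adjusted p = 0.0122). The others were Insig1, a sterol-regulated membrane protein (-0.57 ± 0.11, adjusted p = 0.0152), and Lss, lanosterol synthase (-0.72 ± 0.14, adjusted p = 0.0196). Of 8 fits that each left out 1 array, Fdps passed in 7, Acat2 in 4, Insig1 in 3 and Lss in 2 (adjusted p up to 0.118). Adjusted over the list alone 12 fell, and all 20 had a negative mean change (set test adjusted p = 8.21e-11, and adjusted p = 0.0457 with an estimated correlation). Apoc2, an apolipoprotein that activates lipoprotein lipase, fell by 1.27 ± 0.19 on the log2 scale (adjusted p = 0.00412). Abcg1, a sterol exporter, fell by 1.14 ± 0.16 (adjusted p = 0.00242) on its brightest probe set, while its other probe set had a change of 0.54, and with the mean of a gene's probe sets it changed by -0.30 (adjusted p = 0.556). The GAPDH ratio was 1.41 times as high on the iodide arrays, as a geometric mean.

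**Figure D1:**
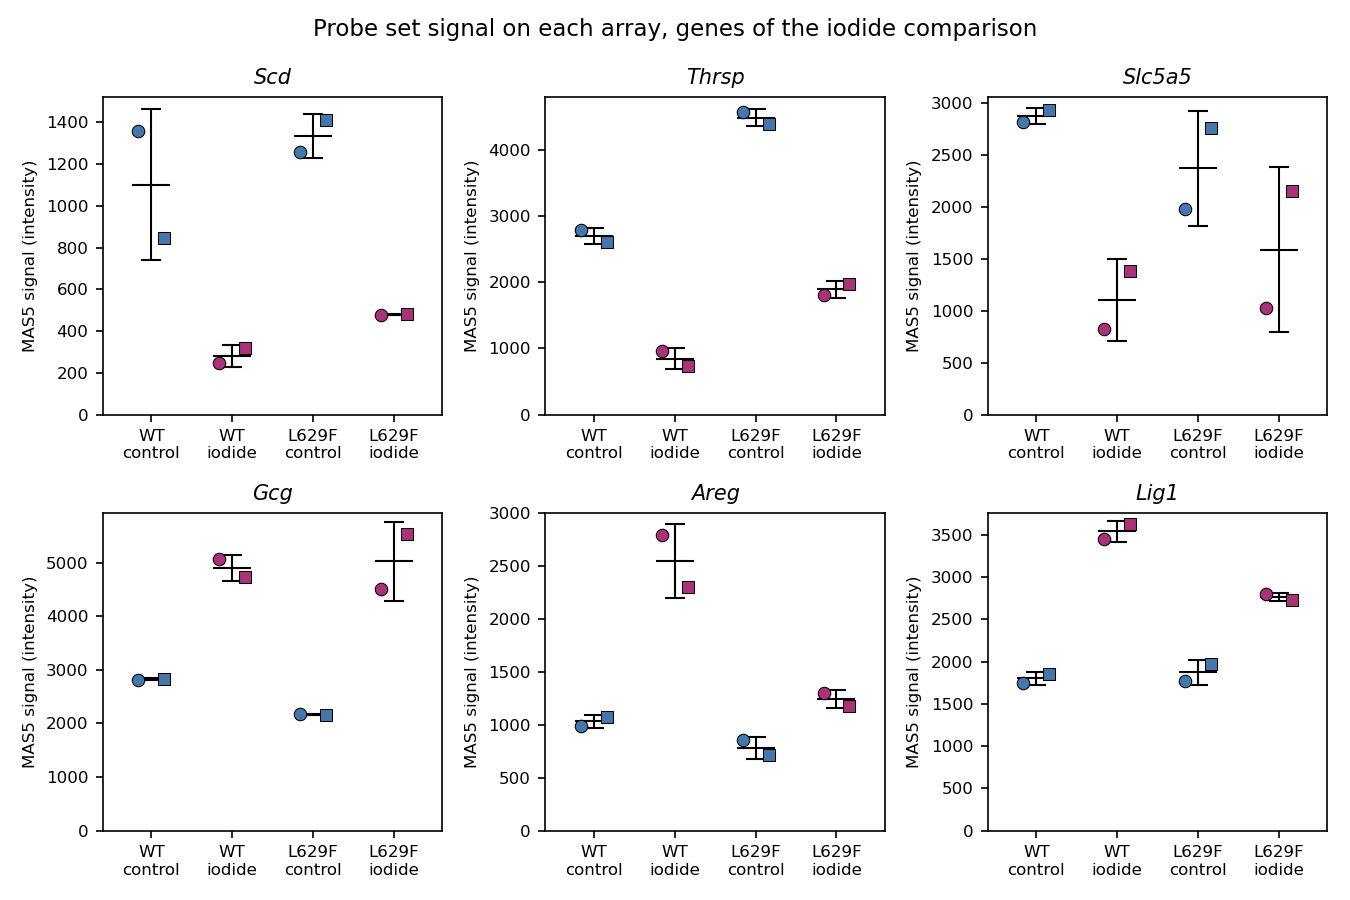
Signal (MAS5 intensity, linear axis) of 6 genes on each array, by receptor line and treatment, where circles are replicate 1, squares replicate 2, and bars the mean ± SD (n = 2). In each line both iodide arrays lie below both control arrays for Scd and Thrsp and above them for Gcg, Areg and Lig1, while for Slc5a5 the arrays of the L629F line overlap.

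Genes of DNA replication and cell division were higher with iodide. Lig1, the DNA ligase of replication, rose by 0.76 ± 0.10 (adjusted p = 0.00125), Rrm1, a subunit of ribonucleotide reductase, by 0.49 ± 0.09 (adjusted p = 0.0146), and Mcm7 and Mcm6, parts of the replicative helicase, by 0.42 ± 0.09 and 0.53 ± 0.11 (adjusted p = 0.029 for each). With Mcm5 and Fen1 these made 6 of 26 measured genes of the DNA replication and G1/S list that rose, and none fell. When adjusted over the list alone 11 rose and 1, E2f1, fell. The set test gave an adjusted p of 2.05e-05, and adjusted p = 0.0457 with an estimated correlation. Of 28 mitotic genes, 26 had a positive mean change and 1, Cdc20, an activator of the anaphase-promoting complex, passed the threshold (0.48 ± 0.11, adjusted p = 0.0456). In this list 3 rose adjusted over the list alone. Of 8 fits that each left out 1 array, Cdc20 passed in 0 (adjusted p up to 0.196), Mcm7, Mcm5 and Fen1 in 1 (0.162, 0.228 and 0.19), Mcm6 in 2 (0.165) and Rrm1 in 4 (0.109). The mitotic list was higher as a set (adjusted p = 2.05e-05, and adjusted p = 0.0457 with an estimated correlation).

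The largest single rises with iodide were those of Gcg, the precursor gene of glucagon and GLP peptides, and Areg, which encodes the growth factor amphiregulin. Gcg went from 2822 ± 18.2 to 4901 ± 241 in wild type and from 2164 ± 17.3 to 5020.4 ± 734 in L629F cells (SD, n = 2 per group), a mean log2 change of 0.99 ± 0.10 (adjusted p = 0.000353). Areg rose by 0.96 ± 0.12 (adjusted p = 0.00106). Nr4a3, an orphan nuclear receptor induced by cAMP, Nrip3, Gpnmb, Etnk1, an ethanolamine kinase, Dtd1 and the nucleolar genes Nop56 and Gnl3 rose by 0.59 to 0.91. Among matrix and adhesion genes Fn1, fibronectin, fell by 1.07 ± 0.15 (adjusted p = 0.00242), Sparc by 1.02 ± 0.13 (adjusted p = 0.00174), Lamb3, a laminin chain, by 1.13 ± 0.14 (adjusted p = 0.00113) and Abi3bp by 1.52 ± 0.31 (adjusted p = 0.0253). The iodide signals of Abi3bp (37.1 and 55.8) lay under the level below which genes were left out as dim (69.9), so the size of its change depends on the pseudocount. It ran from -2.36 to -0.84 over the alternatives, and Abi3bp passed in 2 of 8 fits without 1 array (adjusted p up to 0.174). Lypd2, Cpz, a carboxypeptidase, and the water channel Aqp4 fell by 1.28, 1.24 and 1.07. With the mean of a gene's probe sets, Aqp4 changed by -0.71 (adjusted p = 0.0521) and Nrip3 by 0.52 (adjusted p = 0.0545). The TGF-beta response and extracellular matrix list, with 4 of 22 genes lower (Sparc, Fn1, Col4a1 and Spp1; adjusted over the list alone 6 lower and 2 higher), was lower as a set (adjusted p = 0.000723, and adjusted p = 0.147 with an estimated correlation). Without 1 array, Col4a1 passed in 4 of 8 fits and Spp1 in 3 (adjusted p up to 0.0894 and 0.134).

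Further lists moved by less. Lysosomal genes had a median change of -0.13 (adjusted p = 0.000723, and adjusted p = 0.0722 with an estimated correlation), with the proteases Ctsd (-0.56 ± 0.11) and Cpq (-0.53 ± 0.12) lower. Of the 27, 5 were lower and 1 higher adjusted over the list alone. The unfolded protein response list had a median of -0.07 (adjusted p = 0.00825, and adjusted p = 0.119 with an estimated correlation), and Pdia4, a disulfide isomerase of the endoplasmic reticulum, fell by 0.80 ± 0.13. Adjusted over the list alone 3 of 27 were lower. The interferon and MHC list had a median of -0.10 (adjusted p = 0.0159, and adjusted p = 0.132 with an estimated correlation), and Cd74, the MHC class II invariant chain, fell by 0.77 ± 0.12. In this list 5 of 27 were lower and 2 higher adjusted over the list alone. In the hypoxia and glycolysis list (median -0.10, adjusted p = 0.0313, and adjusted p = 0.439 with an estimated correlation) Bnip3 and Egln3 fell and Pgk1, a glycolytic enzyme, rose. Of the 25, 3 were lower and 1 higher adjusted over the list alone. Heat shock proteins had a median of 0.11 (adjusted p = 0.036, and adjusted p = 0.175 with an estimated correlation), with the mitochondrial chaperone Hspd1 higher by 0.47 ± 0.08. Adjusted over the list alone 4 of 15 were higher. The respiratory chain list had a median of 0.14 with no gene past the threshold, over all genes or adjusted over the list alone (adjusted p = 0.000229, and adjusted p = 0.322 with an estimated correlation), and under quantile scaling its median was 0.01 (adjusted p = 0.734). The hypoxia call was lost without wild type control replicate 2 (adjusted p = 0.123) or wild type iodide replicate 1 (0.321), or with the lowest 60% of probe sets left out (0.0733). The interferon and MHC call was lost with the GAPDH ratio as a covariate (0.189), without the 2 arrays of highest GAPDH ratio (0.067), without wild type iodide replicate 2 (0.0554) or without L629F control replicate 1 (0.0567). The heat shock call was lost without wild type control replicate 2 (0.0639), wild type iodide replicate 1 (0.116), L629F control replicate 1 (0.0584), L629F iodide replicate 1 (0.0521) or L629F iodide replicate 2 (0.0734). It was also lost with the mean of a gene's probe sets (0.147), with quantile scaling (0.124) and without the 2 arrays of highest GAPDH ratio (0.0607). Of the 8 fits without 1 array, Egln3 passed in 0 (adjusted p up to 0.197), Pgk1 and Cpq in 1 (0.235 and 0.204), Ctsd in 2 (0.174), Bnip3 and Hspd1 in 4 (0.0975 and 0.0875), Pdia4 in 6 (0.0875) and Cd74 in 7 (0.0511). With quantile scaling the change of Pgk1 was 0.08 (adjusted p = 0.56).

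Among genes of thyroid function, Slc5a5, the sodium-iodide symporter that brings iodide into the cell, fell with iodide by 1.02 ± 0.21 on average (adjusted p = 0.0258), from 2873 ± 77.1 to 1105 ± 396 in wild type cells and from 2370.4 ± 553 to 1588 ± 794 in L629F cells (SD, n = 2 per group). Hhex, a homeobox gene of thyroid development, rose by 0.38 ± 0.09 (adjusted p = 0.0434). The values of Duox2, the peroxide-making oxidase of the thyroid (-0.22 ± 0.11, adjusted p = 0.351), Dio1, a deiodinase (-0.05 ± 0.15, adjusted p = 0.903), and the transcription factors Pax8 (-0.08 ± 0.11, adjusted p = 0.794), Nkx2-1 (0.06 ± 0.12, adjusted p = 0.857) and Foxe1 (0.10 ± 0.09, adjusted p = 0.655) did not pass. A dimmer probe set of Pax8 went from 2570 ± 545 to 1677 ± 540 with iodide in wild type cells. In L629F cells it went from 2107 ± 457 to 1868 ± 354 (SD, n = 2 per group). The rat Tshr probe set gave -0.45 ± 0.16 (adjusted p = 0.19) and is no check on the human receptor that was introduced. For Tg, thyroglobulin, the brightest probe set gave -0.16 ± 0.09 (adjusted p = 0.457) and the other one 0.58, opposite in sign. The thyroid list as a whole did not differ (15 measured genes, median -0.05, adjusted p = 0.61). Slc5a5 was lower and Hhex higher when adjusted over the list alone. The lists of NRF2 targets (adjusted p = 0.266), p53 targets (0.339), peroxide and superoxide removal (0.61) and cAMP-responsive genes (0.955) did not pass, nor did the leucocyte markers (median 0.09, adjusted p = 0.955). Hhex passed in 1 of 8 fits that each left out 1 array (adjusted p up to 0.225) and Slc5a5 in 3 (up to 0.142). Slc5a5 did not pass without either wild type control array, wild type iodide replicate 1, L629F control replicate 2 or L629F iodide replicate 1.

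In all, 167 genes passed for the average over both lines, 55 higher and 112 lower, 15 of them by at least 1 log2, and 1531 genes had an unadjusted p under 0.05 where 502 would by chance. Of the 21 genes named by size or among the thyroid genes that passed, 14 also passed in every fit without 1 array: Gcg, Areg, Nrip3, Lig1, Etnk1, Scd, Thrsp, Lypd2, Apoc2, Cpz, Abcg1, Lamb3, Aqp4 and Fn1. Of these, Abcg1, Aqp4 and Nrip3 did not pass with the mean of a gene's probe sets. The number of genes past the threshold was 38 and 44 without wild type control replicates 1 and 2, 266 without wild type iodide replicate 1, 82 and 54 without L629F control replicates 1 and 2, and 61 without L629F iodide replicate 1. It split into 37 higher and 131 lower with quantile scaling and into 99 higher and 96 lower with arrays centred on the median of all probe sets, and was 18 without the intensity trend.

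In wild type cells given iodide, lipid genes were again among those that fell. Scd changed by -1.82 ± 0.22 (SE, n = 2 arrays per group, adjusted p = 0.00293), Thrsp by -1.65 ± 0.16 (adjusted p = 0.000625) and Elovl6 by -1.03 ± 0.19 (adjusted p = 0.034). Srebf1, the transcription factor of lipid synthesis, also fell (adjusted p = 0.0419). With Fasn these were 5 of 16 fatty acid synthesis genes lower, 9 adjusted over the list alone (set test adjusted p = 4.2e-12, and adjusted p = 0.0375 with an estimated correlation). All 20 cholesterol synthesis genes had a negative mean change (median -0.46), with Fdps and Insig1 past the threshold and 8 adjusted over the list alone (set test adjusted p = 1.97e-12, and adjusted p = 0.0675 with an estimated correlation). Cyp2f4, a cytochrome P450, Cpz, Lypd2, the lipid kinase Pip5k1a, the protease Adam10, Aplp2, a relative of the amyloid precursor, and Gpc4, a glypican, fell by 1.29 to 1.69. The change of Adam10 ran from -1.69 to -0.96 over the alternatives, and its call was lost under most of them. Another probe set of Aplp2 went the other way, and with the mean of a gene's probe sets the changes of Aplp2 and Nrip3 were -0.69 and 0.56 (adjusted p = 0.199 and 0.185). Sparc (-1.38 ± 0.19), Fn1 and Col4a1 fell among the matrix genes, 3 of 22 and 6 adjusted over the list alone (set test adjusted p = 0.000256, and adjusted p = 0.168 with an estimated correlation). Of the 8 fits without 1 array, Srebf1 (-1.32 to -0.67, adjusted p up to 0.433), Fasn (0.41) and Insig1 (0.391) passed in 1, Fdps (0.314) and Col4a1 (0.325) in 4, and Elovl6 (0.33) and Fn1 (0.346) in 5. Areg rose by 1.27 ± 0.17 (adjusted p = 0.00466). Gpnmb, Lig1, Nrip3, Gcg, Etnk1, the phosphate transporter Slc20a1 and COX2, the mitochondrial subunit of cytochrome c oxidase, rose by 0.65 to 1.09. The signal of COX2 was high, at 18406.4 without and 31475 with iodide, and its change ran from 0.30 (with quantile scaling, where it did not pass) to 0.97 and it passed in 3 of 8 fits without 1 array. Ddx21 (0.82 ± 0.17, adjusted p = 0.0551, its other probe set -0.75) and Ttc9 (0.69 ± 0.14, adjusted p = 0.0565) did not pass. Slc5a5 did not pass within this line (-1.40 ± 0.29, adjusted p = 0.0617).

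Of the smaller lists in wild type cells, DNA replication was higher (median 0.26, adjusted p = 0.00902, and adjusted p = 0.168 with an estimated correlation), with Lig1 past the threshold. Of the 26, 8 were higher and 2 lower adjusted over the list alone, and the call was lost without wild type control replicate 2 (0.0701). Lysosomal genes were lower (median -0.12, adjusted p = 0.0139, and adjusted p = 0.168 with an estimated correlation), with 3 lower and 1 higher of 27 adjusted over the list alone. That call was lost without wild type control replicate 2 (0.0718) or wild type iodide replicate 1 (0.0911). The same arrays decided the hypoxia and glycolysis list (median -0.18, adjusted p = 0.0196, and adjusted p = 0.417 with an estimated correlation), at 0.141 and 0.525 without them. In this list 2 of 25 were lower and 1 higher adjusted over the list alone. The respiratory chain list (median 0.14, adjusted p = 0.0323, and adjusted p = 0.516 with an estimated correlation), with no member past the threshold, lost its call without wild type control replicate 1 (0.462), wild type iodide replicate 2 (0.197) or L629F iodide replicate 1 or 2 (0.0517 and 0.051), and its median was -0.01 under quantile scaling (0.708). It was lost as well with the lowest 60% of probe sets left out (0.0514), with the GAPDH ratio as a covariate (0.243) and without the 2 arrays of highest GAPDH ratio (0.248). In total 47 genes passed in wild type cells, 8 higher and 39 lower (8 and 16 with arrays centred on the median of all probe sets), with 1261 at an unadjusted p under 0.05. limma called 0 genes without wild type control replicate 1 (842 at an unadjusted p under 0.05) and 0 without the intensity trend (1070), 2 without wild type control replicate 2 and 23 without wild type iodide replicate 2. Of the 18 genes named by size that passed, 0 passed in every fit without 1 array.

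In L629F cells, Gcg rose with iodide by 1.19 ± 0.14 (SE, n = 2 arrays per group, adjusted p = 0.00706), and 8 genes fell. These were Scd (-1.41 ± 0.22, adjusted p = 0.0312), Thrsp (-1.23 ± 0.16, adjusted p = 0.0095), Acsl1 (-0.90 ± 0.14, adjusted p = 0.0289), the cholesterol exporter Abca1 (-0.98 ± 0.15, adjusted p = 0.0289), Lamb3, Smtnl2, Tnnt2, a troponin, and Cpe, a carboxypeptidase that processes prohormones, the last 4 by 0.83 to 1.19. Sema3c and Ddit4, an inhibitor of mTOR signalling, did not pass (-1.16 ± 0.20 and -1.16 ± 0.20, adjusted p = 0.0532 for each), nor did Etnk1 (0.65 ± 0.12, adjusted p = 0.0587), Nrip3 (0.75 ± 0.14, adjusted p = 0.077), Rrm1, Nuf2 and Tmem192 (adjusted p = 0.152 for each). Of 16 fatty acid synthesis genes 3 fell, 11 adjusted over the list alone (set test adjusted p = 1.65e-16, and adjusted p = 0.0196 with an estimated correlation). Mitotic genes had a positive mean change in 26 of 28, with a median of 0.25 and none past the threshold even adjusted over the list alone (set test adjusted p = 8.34e-09, and adjusted p = 0.029 with an estimated correlation). DNA replication genes had a positive mean change in 23 of 26, with 5 higher adjusted over the list alone (set test adjusted p = 2.38e-06, and adjusted p = 0.0393 with an estimated correlation). Cholesterol synthesis genes had a median of -0.21, with none past the threshold and 2 of 20, Lss and Acat2, lower adjusted over the list alone (set test adjusted p = 0.000391, and adjusted p = 0.159 with an estimated correlation, 0.0519 without L629F iodide replicate 2). Slc5a5 gave -0.64 ± 0.29 (adjusted p = 0.601).

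The other lists past the set test in L629F cells had no member past the threshold. The respiratory chain (median 0.16, adjusted p = 0.000117, and adjusted p = 0.353 with an estimated correlation) was higher, and under quantile scaling its median was 0.02 (adjusted p = 0.376). Lysosomal genes (median -0.18, adjusted p = 0.0051, and adjusted p = 0.143 with an estimated correlation), interferon and MHC genes (-0.19, adjusted p = 0.0146, and adjusted p = 0.15 with an estimated correlation) and the unfolded protein response (-0.11, adjusted p = 0.0164, and adjusted p = 0.15 with an estimated correlation) were lower. When adjusted over the list alone, Cd74 and RT1-Da were lower among the interferon and MHC genes and no gene passed in the other 3 lists. Each of these calls was lost without L629F iodide replicate 2 (adjusted p = 0.0519 in every case). Without L629F control replicate 1 the lysosomal (0.0757), interferon and MHC (0.11) and unfolded protein response (0.0541) calls were lost. Without L629F iodide replicate 1 the latter pair was lost (0.0503 and 0.065), and without L629F control replicate 2 the unfolded protein response (0.0664). All 4 were lost without the 2 arrays of highest GAPDH ratio (0.051 in every case), and the interferon and MHC call also with the GAPDH ratio as a covariate (0.0733) and with no filter on dim probe sets (0.0558). With 825 genes at an unadjusted p under 0.05, the 9 genes past the threshold fell to 3 without either wild type control array and 2 without L629F iodide replicate 1. limma called 0 without L629F control replicate 1 (660 at an unadjusted p under 0.05), L629F control replicate 2 (688), L629F iodide replicate 2 (711) or the intensity trend (762), and 1 higher and 1 lower with arrays centred on the median of all probe sets. Of the 9, 0 passed in every fit without 1 array.

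Scd, Thrsp, Lamb3, Smtnl2, Tnnt2 and Gcg passed in both lines, all in the same direction, where independent lists would share 0.03 lower genes. Of the 47 genes called in wild type cells 45 had the same sign in L629F cells, and of the 9 called in L629F cells all 9 had the same sign in wild type cells. The group means shared no array, but the spread was estimated once from all 8 arrays, so the lists of the lines were not independent. Across all genes the changes in the lines correlated at 0.29 (genes are not independent replicates). The difference between the lines itself had a median SE of 0.29 log2, against 0.20 for a change within a line. The simulated data held no such difference, so its recovery was not measured. For this difference limma called 0 genes, which does not show that the lines respond alike. There were 419 at an unadjusted p under 0.05 where chance gives 502. The smallest adjusted p of any gene was 0.434. That gene was Pip5k1a (interaction 1.86 ± 0.31), with signals of 474 and 157 without and with iodide in wild type cells and 327 and 464 in L629F cells. The next by p were Aplp2 (1.21 ± 0.23, adjusted p = 0.712, its other probe sets had the opposite sign), Zswim8, Adam10 and Abi3 upward and Pin4 (-1.42 ± 0.29), Mtif2, Cyfip1, Serf1 and Shtn1 downward (adjusted p = 0.993 for each). The interaction of Slc5a5 was 0.76 ± 0.42 (adjusted p = 0.993). As sets, cholesterol synthesis genes had a positive interaction (median 0.28, 17 of 20 positive, adjusted p = 0.000612, and adjusted p = 0.457 with an estimated correlation), their median change being -0.46 in wild type and -0.21 in L629F cells. Mitotic genes did too (median 0.19, 20 of 28 positive, adjusted p = 0.0101, and adjusted p = 0.457 with an estimated correlation), with medians of 0.10 and 0.25. In neither list did a gene pass, over all genes or adjusted over the list alone, and fry called 0 lists. The mitotic call was lost without wild type control replicate 1 (0.0578), wild type iodide replicate 2 (0.124) or L629F iodide replicate 1 (0.0667), and without the 2 arrays of highest GAPDH ratio (0.158).

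**Figure D2:**
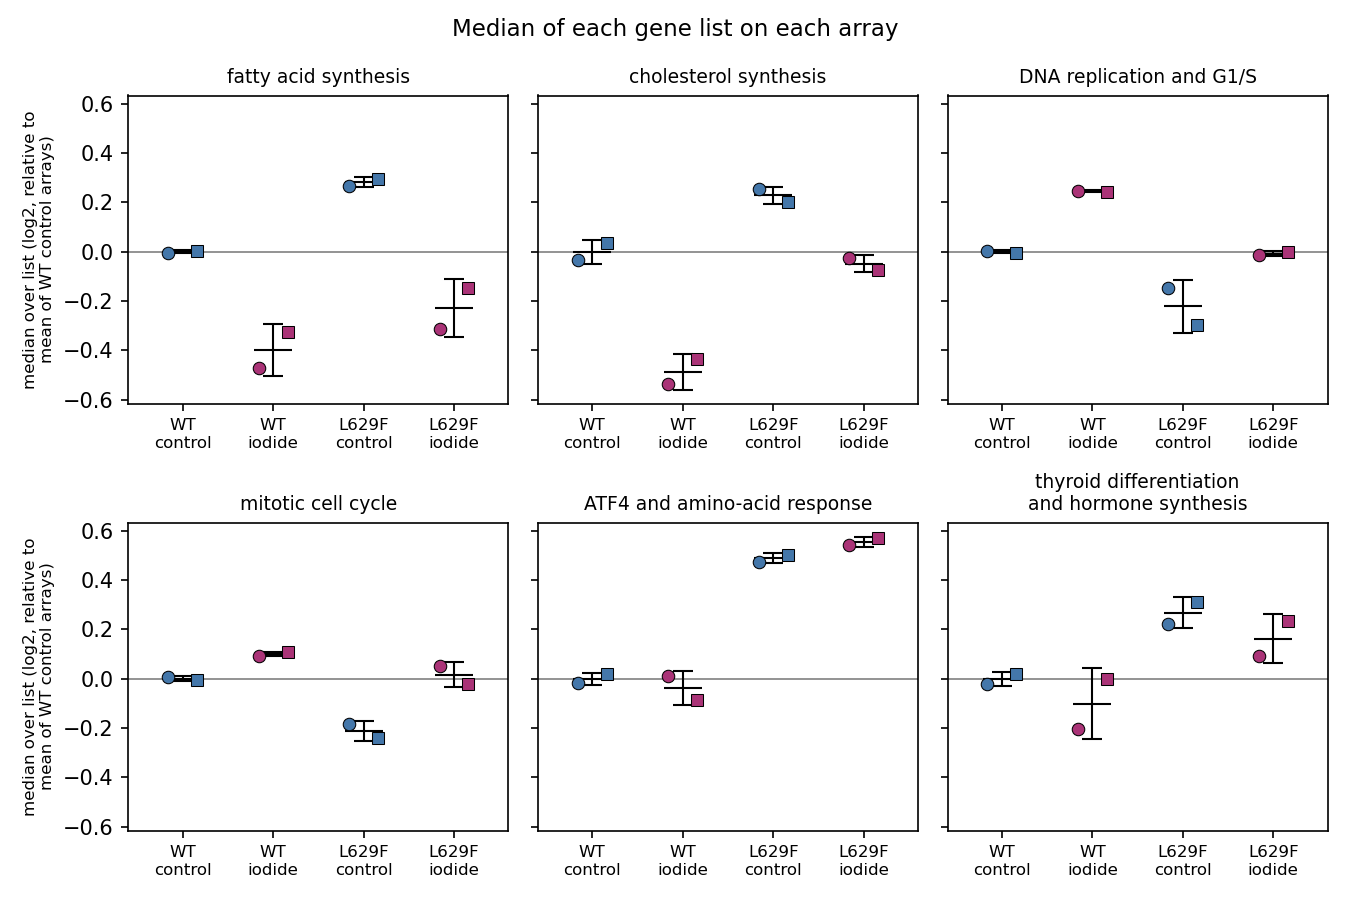
Median over the measured genes of 6 lists on each array (log2, relative to each gene's mean over the wild type control arrays, which therefore lie around 0), where circles are replicate 1, squares replicate 2, and bars the mean ± SD (n = 2). Iodide arrays lie below the control arrays of their line for both lipid lists and above them for DNA replication and mitosis, and the ATF4 list is higher on all 4 L629F arrays.

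The comparison of receptors asked how cells with the constitutively active receptor differ from those with the wild type receptor. Without iodide, L629F cells had higher levels of genes of the ATF4 and amino-acid response. Nupr1, a stress-induced chromatin protein, had a signal of 3621 ± 508 against 1197 ± 108 (SD, n = 2 per group), a log2 difference of 1.57 ± 0.15 (SE, adjusted p = 0.000961). Chac1, which degrades glutathione, was higher by 1.41 ± 0.16 (adjusted p = 0.00196), the cystine transporter Slc7a11 by 1.46 ± 0.24 (adjusted p = 0.0211) and Sesn2, a stress-induced inhibitor of mTOR signalling, by 0.84 ± 0.16 (adjusted p = 0.038). With Psph these were 5 of 27 genes of the list, 14 higher and 1 lower adjusted over the list alone (median 0.51, set test adjusted p = 7.98e-11, and adjusted p = 0.0508 with an estimated correlation). The MHC class II genes RT1-Da (1.66 ± 0.24, adjusted p = 0.0105), RT1-Db1 (1.67 ± 0.29, adjusted p = 0.0277) and Cd74 (0.88 ± 0.17, adjusted p = 0.0419) and the interferon-induced Ifit2 (2.01 ± 0.38, adjusted p = 0.0381) were higher. These were 4 of 27 in their list, and 6 were higher and 1 lower adjusted over the list alone (adjusted p = 0.00435, and adjusted p = 0.104 with an estimated correlation). Col4a6, a collagen IV chain, was higher by 2.51 ± 0.28 (adjusted p = 0.00138), as were the acute-phase gene Saa3, the Wnt antagonist homologue Dkk3, Serpinf1, which encodes the secreted factor PEDF, the sulfotransferase Gal3st4 and Ucp1, the uncoupling protein of brown fat, by 1.58 to 2.04. The wild type signals of Col4a6 (60.1), Saa3 (57.0), Ifit2 (49.7) and Dkk3 lay under the level for dim genes (69.9), so the size and rank of these differences depend on the pseudocount. Over the alternatives they ran from 1.73 to 3.08 for Col4a6, 1.28 to 2.75 for Saa3, 1.22 to 2.79 for Ifit2 and 1.00 to 2.32 for Dkk3. Of the 8 fits without 1 array, Saa3 passed in 5, Ifit2 in 4 (adjusted p up to 0.296) and Dkk3 in 1. Cavin3, a caveolar coat protein, was lower by -1.92 ± 0.24 (adjusted p = 0.00397) and Mest, an imprinted gene, by -1.17 ± 0.18 (adjusted p = 0.013). Pdzrn3, Fbp2, Fam83d, the stress gene Gadd45a, Nutf2, Rabac1, the actin-binding profilin Pfn1 and Igfbp7 were lower by 0.94 to 1.39. Another probe set of Nutf2 did not go the same way, and with the mean of a gene's probe sets it gave -0.32 (adjusted p = 0.435). Among list members, Cd74 (0.64 to 1.12, adjusted p up to 0.29) and Psph (0.365) passed in 2 of 8 fits without 1 array, Slc7a11 (0.235) and Sesn2 (0.279) in 4 and Chac1 (0.0737) in 7.

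Genes of the cell cycle were lower in L629F cells without iodide, 25 of 28 mitotic genes (median -0.20, set test adjusted p = 9.23e-06, and adjusted p = 0.0593 with an estimated correlation) and 23 of 26 DNA replication genes (median -0.25, adjusted p = 5.98e-05, and adjusted p = 0.0593 with an estimated correlation) having a negative mean difference. No member passed, over all genes or adjusted over the list alone. Fatty acid synthesis genes were higher (median 0.31, adjusted p = 6.85e-05, and adjusted p = 0.0593 with an estimated correlation), with Acsl1 past the threshold (0.68 ± 0.14, adjusted p = 0.0486, in 2 of 8 fits without 1 array, adjusted p up to 0.359) and 3 adjusted over the list alone. The thyroid list was higher (median 0.25, adjusted p = 0.011, and adjusted p = 0.33 with an estimated correlation), with no member past the threshold over all genes and 4 higher and 1 lower adjusted over the list alone. Its smallest p-values were those of Crym, a thyroid hormone binding protein (0.83 ± 0.17, adjusted p = 0.0517), Duox2 (0.60 ± 0.15, adjusted p = 0.106), Dio1 (0.71 ± 0.21, adjusted p = 0.176) and Foxe1 (-0.40 ± 0.12, adjusted p = 0.193). Slc5a5 gave -0.29 ± 0.29 (adjusted p = 0.719). Without wild type control replicate 1 or L629F control replicate 2 the thyroid call was lost (adjusted p = 0.0562 and 0.186), as it was with the GAPDH ratio as a covariate (0.191). Cholesterol synthesis genes (median 0.24, adjusted p = 0.0136, and adjusted p = 0.33 with an estimated correlation) had Sc5d alone higher adjusted over the list alone, and the call was lost with the GAPDH ratio as a covariate (0.124) and without wild type control replicate 1 (0.0776) or L629F control replicate 1 (0.0871). The respiratory chain list (median -0.10, adjusted p = 0.00922, and adjusted p = 0.507 with an estimated correlation) had no member past the threshold and lost its call without wild type control replicate 2 (0.214) or L629F control replicate 2 (0.191) and with quantile scaling (0.104). The leucocyte markers gave a median of 0.47 over 5 genes (adjusted p = 0.215). In total 49 genes passed, 34 higher and 15 lower, with 1370 at an unadjusted p under 0.05. The count was 4 and 9 without wild type control replicates 1 and 2, 5 and 8 without L629F control replicates 1 and 2, and 30 without L629F iodide replicate 1. Of the 20 genes named by size that passed, 2, Col4a6 and Nupr1, passed in every fit without 1 array. Centring on the median of all probe sets lowered the median receptor difference over all genes by 0.16 without and 0.18 with iodide. Relative to that shift 18 genes were higher and 73 lower, and the median of the interferon and MHC list was -0.02.

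With iodide present, genes of the ATF4 list were again higher in L629F cells. Nupr1 was higher by 1.51 ± 0.15 (SE, n = 2 arrays per group, adjusted p = 0.000643), Chac1 by 1.44 ± 0.16 (adjusted p = 0.00157), the amino acid transporter Slc7a5 by 1.16 ± 0.18 (adjusted p = 0.0161) and Sesn2 by 0.92 ± 0.16 (adjusted p = 0.0217). These were 4 of 27 genes of the list, 15 higher and 2 lower adjusted over the list alone (median 0.50, set test adjusted p = 4.31e-12, and adjusted p = 0.0412 with an estimated correlation). Cyp2f4 was higher by 1.64 ± 0.14 (adjusted p = 0.000263) and Serpinf1 by 2.00 ± 0.21 (adjusted p = 0.000643). Col12a1, Ppp1r3b, a glycogen-targeting subunit of a phosphatase, Icam5, Ucp1, RT1-Db1, Col4a6 and Gal3st4 were higher by 1.47 to 2.04. The wild type iodide signals of Col12a1 (18.6), Icam5 (18.2) and Ppp1r3b (22.5) lay under the level for dim genes (69.9), and over the alternatives their differences ran from 1.06 to 3.53, 0.91 to 3.40 and 1.04 to 3.08. Col12a1, Icam5, Ppp1r3b and Col4a6 passed in 0 of 8 fits without 1 array (adjusted p up to 0.247). Cavin3 (-1.79 ± 0.24, adjusted p = 0.00646), Mest (-1.24 ± 0.18, adjusted p = 0.0092) and Areg (-1.01 ± 0.17, adjusted p = 0.0194) were lower, as were the AP-1 gene Junb, Pdzrn3, Vps33a, Ing3, Gadd45a, Zfp637 and Cop1, by 0.76 to 1.79. The L629F iodide signal of Junb (37.8) was dim as well, and its difference ran from -2.52 to -1.03, past the threshold in 1 of 8 fits without 1 array (adjusted p up to 0.164). Vps33a, Ing3, Gadd45a, Zfp637 and Cop1 passed in 0 of these. Other probe sets of Vps33a and Ing3 did not go the same way. With the mean of a gene's probe sets these gave -0.19 and -0.42 (adjusted p = 0.773 and 0.449), and RT1-Db1 was higher by 1.12 (adjusted p = 0.0878). Among list members, Sesn2 passed in 3 of 8 fits without 1 array (adjusted p up to 0.169), Slc7a5 (0.139) and Cd74 (0.123) in 5 and Thrsp (0.0789) in 7. Cholesterol synthesis genes were higher (median 0.40), with Fdps (0.67 ± 0.12, adjusted p = 0.0348), Sc5d and Dhcr7 past the threshold and 7 of 20 adjusted over the list alone (set test adjusted p = 2.15e-10, and adjusted p = 0.0774 with an estimated correlation). Without 1 array, Fdps, Sc5d and Dhcr7 passed in 0 of 8 fits (adjusted p up to 0.204, 0.199 and 0.19). Among 16 fatty acid synthesis genes Thrsp passed (1.14 ± 0.16, adjusted p = 0.00646), 6 adjusted over the list alone (set test adjusted p = 8.05e-05, and adjusted p = 0.0774 with an estimated correlation). The median of this list was 0.20, and 0.01 with arrays centred on the median of all probe sets. Without iodide the same values were 0.31 and 0.15.

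The thyroid list was higher with iodide as well (median 0.20, adjusted p = 0.000773, and adjusted p = 0.182 with an estimated correlation, 0.0719 without wild type iodide replicate 1 and 0.0676 with no filter on dim probe sets), with no member past the threshold, over all genes or adjusted over the list alone. With arrays centred on the median of all probe sets, the median of the thyroid list was 0.02 with and 0.10 without iodide. Cdh16, an adhesion protein of thyroid epithelium, gave 0.96 ± 0.30 (adjusted p = 0.218) and Slc5a5 0.46 ± 0.29 (adjusted p = 0.554). DNA replication genes were lower (median -0.20, adjusted p = 0.00371, and adjusted p = 0.126 with an estimated correlation), again with no member past the threshold either way. Interferon and MHC genes were higher (median 0.10, adjusted p = 0.0109, and adjusted p = 0.143 with an estimated correlation, 0.105 without wild type iodide replicate 2 and 0.136 without the 2 arrays of highest GAPDH ratio), with Cd74 (1.13 ± 0.17, adjusted p = 0.0151) and RT1-Db1 past the threshold and 4 adjusted over the list alone, and their median was -0.08 with arrays centred on the median of all probe sets. The leucocyte markers gave a median of 0.33 over 5 genes (adjusted p = 0.672). In total 51 genes passed, 37 higher and 14 lower, with 1217 at an unadjusted p under 0.05, and 17 higher and 53 lower with that centring. Of these, 19 genes passed both without and with iodide, 15 higher and 4 lower (Cavin3, Gadd45a, Mest and Pdzrn3), where independent lists would share 0.13 and 0.02, and across genes the receptor differences correlated at 0.45. The group means shared no array here either, but the spread did, so these lists were not independent. The count with iodide was 8 without either L629F iodide array, 21 and 24 without wild type iodide replicates 1 and 2, 17 without either wild type control array and 23 and 25 without L629F control replicates 1 and 2. Of the 20 genes named by size that passed, 3, Cyp2f4, Nupr1 and Serpinf1, passed in every fit without 1 array.

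**Figure D3:**
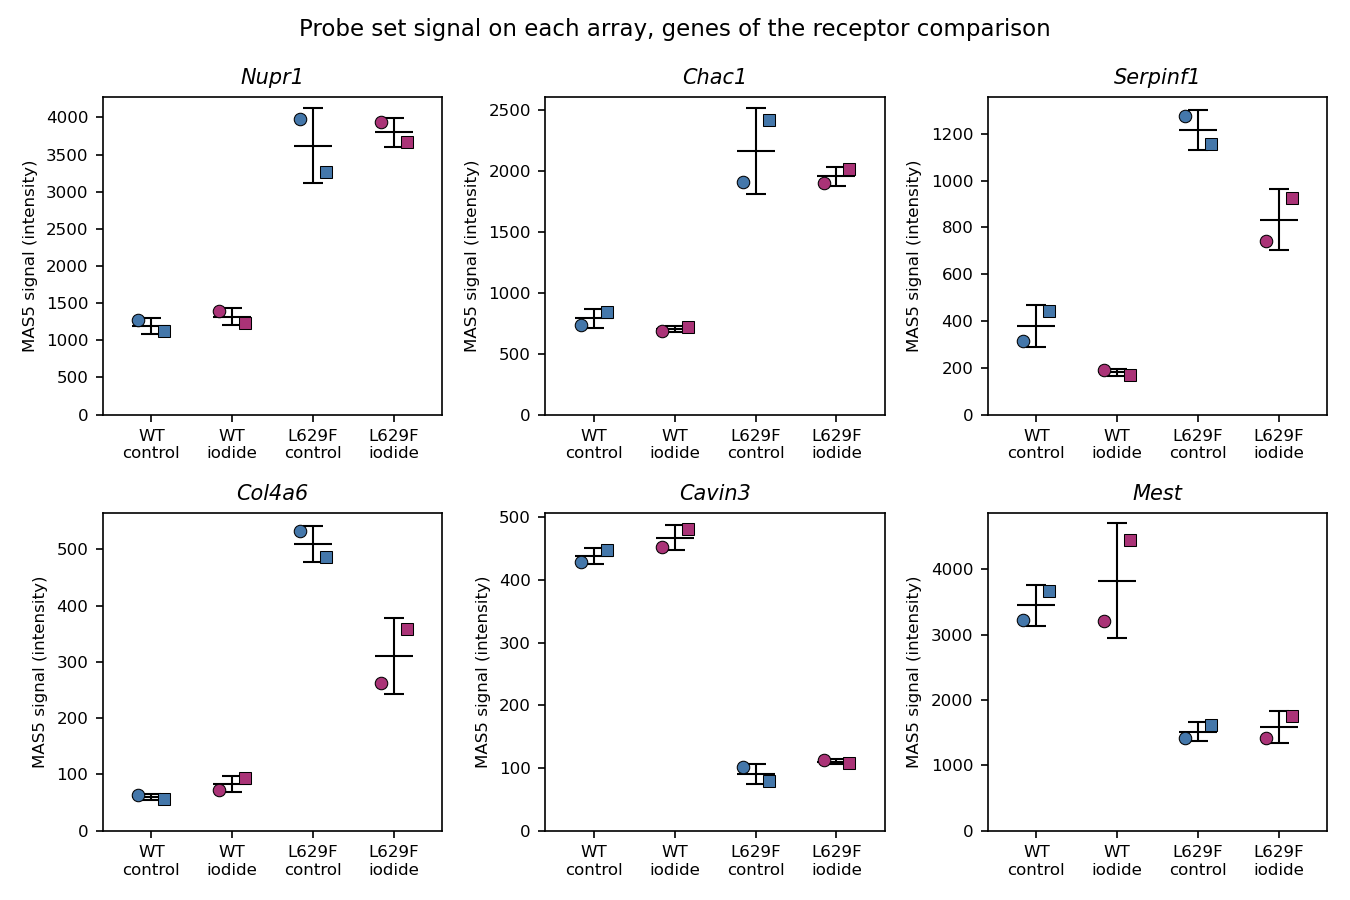
Signal (MAS5 intensity, linear axis) of 6 genes on each array, by receptor line and treatment, where circles are replicate 1, squares replicate 2, and bars the mean ± SD (n = 2). All 4 L629F arrays lie above all 4 wild type arrays for Nupr1, Chac1, Serpinf1 and Col4a6 and below them for Cavin3 and Mest.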

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

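The tests of array scaling, of a low starting level and of each array's list median with the GAPDH ratio were chosen only after the results they bear on had been seen. The cholesterol synthesis genes were picked out because their change with iodide differed between the lines, with a median interaction of 0.28 over 20 genes (adjusted p = 0.000612, and adjusted p = 0.457 with an estimated correlation). For the same reason the mitotic genes were, with a median interaction of 0.19 over 28 genes (adjusted p = 0.0101, and adjusted p = 0.457 with an estimated correlation), and no gene of either list passed. Among data no gene name covers, 26 of 4704 probe sets without a single symbol passed for iodide averaged over both lines, 12 higher and 14 lower, and they are unnamed here. The GAPDH 3′ to 5′ ratio was 1.41 times as high on the iodide as on the control arrays (exact permutation p = 0.171, n = 4 each).

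The fall of the lipid lists with iodide could come from RNA degradation or from the scaling of the arrays. With each array's median over the 36 genes fitted on line, iodide and GAPDH ratio, the iodide term was -0.44 (95% interval -0.58 to -0.30). A linear term for the ratio thus did not remove the fall. The lists were picked on these arrays and the ratio comes from 1 gene, so this does not exclude degradation. Under 3 other scalings the term closest to 0, in a fit without the ratio, was -0.38 (-0.49 to -0.27). These scalings moved the median iodide change over all genes by only 0.004 to 0.028. They could therefore hardly have removed the fall, and scaling is not excluded. The arrays of closest ratio (median -0.54 in wild type and -0.24 in L629F cells) are 1 per side, with no spread between arrays, and percentile 0 of 10000 random lists for the median of -0.37 only repeats why the lists were picked, so neither decides. The beta-actin ratio was not used in these fits. Degradation that the GAPDH ratio does not follow, scaling, background and other differences between the samples stayed open beside an effect of iodide.

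The larger fall of the cholesterol synthesis genes in wild type cells could also reflect degradation, since wild type iodide replicate 2 had the highest GAPDH ratio. Without that array, which leaves 1 wild type iodide array, the median interaction was 0.33, against 0.28 with all arrays. Its 95% interval, 0.08 to 0.56, is over genes and holds no spread between arrays. The lower bound was too low to tell. The list did not start lower in L629F cells, with a median difference of 0.24 (95% interval over genes 0.09 to 0.34). Its median was 0.25 and 0.20 on the L629F control arrays against -0.03 and 0.03 on the wild type ones. The difference was 0.08 to 0.29 under the scalings and turned its direction in 0 of 18 alternatives. Its call as higher was lost with the GAPDH covariate (camera, adjusted p = 0.124) and with an estimated correlation (adjusted p = 0.33). These values argue against a low starting level of this list in these samples, while the size of the difference stayed uncertain. Neither a biological nor a technical origin was settled.

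The higher ATF4 genes of L629F cells could come from degradation, scaling or a difference between the lines unrelated to the receptor. With each array's median over the 27 genes fitted in the same way, the receptor term was 0.49 (95% interval 0.39 to 0.59) beside the GAPDH ratio. A linear term for the ratio thus did not remove the difference. The list was picked on these arrays and the ratio comes from 1 gene, so degradation is not excluded. Under the other scalings the term was closest to 0 when centred on all probe sets, at 0.31 (0.19 to 0.44). The scalings lowered the median receptor difference over all genes by at most 0.16 without and 0.18 with iodide. They could therefore hardly have removed the difference of this list, and scaling is not excluded. Centring on all probe sets lowered the list's median from 0.51 to 0.35 without and from 0.50 to 0.31 with iodide, so its size depends on the scaling. The control arrays of closest ratio (median 0.48) are 1 per side and percentile 100 of the random lists repeats why the list was picked, so neither decides. The labels name 1 line per receptor, so these data could not tell an effect of the receptor from a difference between lines. Degradation, scaling and background stayed open as well. The beta-actin ratio, which was not fitted, was higher on both L629F control arrays (5.93 and 7.90) than on both wild type ones (2.23 and 5.05).

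For the genes past the threshold with iodide, the 8 arrays were split into 4 and 4 in all 34 ways other than by line, in a model with a line term and no interaction, which is not the model behind the 167 genes of the report. Of these, 1 split, the real one, called 209 genes, and the others called at most 11 (7 for the split by replicate number). Only 18 of the splits keep 2 arrays of each line on each side, which is too few for a share under 0.05.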

How the results depend on the processing

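The GAPDH covariate, leaving out the 2 arrays of highest GAPDH ratio and centring on the median of all probe sets were chosen only after the result was seen, and the other alternatives in this part before the data were examined. No named gene past the threshold turned its direction in the alternatives scored gene by gene. Probe sets taken one by one were not scored in this way, and other probe sets of Abcg1 and Aplp2 had the opposite sign. No list past the threshold turned its direction, except small list medians under scaling given with the comparisons. For fatty acid synthesis, the largest adjusted p under any alternative with the preset correlation was 3.77e-14 averaged over both lines. The number of arrays and the signal over background limit the precision for dim genes. The cause was not tested for any value below.

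For iodide averaged over both lines (167 genes), the count was 93 with no filter on dim probe sets, 18 without the intensity trend, 373 at adjusted p under 0.10, 15 at a log2 change of at least 1, 258 with the GAPDH covariate, and 38 to 266 leaving out 1 array. In wild type cells (47) the same gave 15, 0, 87, 22, 194 and 0 to 42, with 24 when centred on all probe sets and 28 from only the arrays compared. In L629F cells (9) they gave 4, 0, 15, 4, 30 and 0 to 9, with 2 centred on all probe sets, 3 from only the arrays compared, 16 with quantile scaling and 3 with probe sets one by one. For the receptor without iodide (49) they gave 14, 10, 98, 26, 265 and 4 to 66, with 91 centred on all probe sets, 87 from only the arrays compared, 83 without the 2 arrays, 31 with the mean of probe sets and 28 one by one. With iodide (51) they gave 14, 21, 104, 28, 135 and 8 to 25, with 6 from only the arrays compared, 7 without the 2 arrays and 32 one by one.

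Replicate numbers were not taken to pair the arrays, since the labels name no shared batch and, of 6 correlations between groups (0.0422 to 0.224, all positive), 2 were under 0.1. Replicate 2 had the higher GAPDH ratio in all 4 groups, and by number the ratio was higher with iodide in all 4 pairs, so a shared handling is not excluded. A replicate block gave 527, 231, 60, 248 and 169 genes in that order. A block within each line gave 839, 463 and 120 for iodide and 2 for the interaction. Lists past the threshold with an estimated correlation were 4 of 11 averaged, 1 of 7 in wild type cells, 3 of 8 in L629F cells, 0 of 8 and 1 of 6 for the receptor, and 0 of 2 for the interaction (0 with fry). The interaction had 4 with no pseudocount, centred arrays, the block or the covariate, 1 without the 2 arrays and 1 to 4 leaving out 1 array. In L629F cells 4 were left without the 2 arrays, and leaving out 1 array left as few as 3 there and 4 in wild type cells.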

Other observations

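The 2 gene lists of the next paragraphs were drawn up after other genes' changes had been seen and leave those genes out, and the window of neighbouring genes was among the tests chosen only after the result was seen. Averaged over both lines, most measured genes of a list for the sterol-sensing nuclear receptor LXR had a negative mean change with iodide. Apoc1, an apolipoprotein, changed by -0.59 ± 0.11 (SE, n = 2 arrays per group, adjusted p = 0.0152), Mylip, which marks the LDL receptor for degradation, by -0.70 ± 0.14 (adjusted p = 0.0258), and Pltp, a phospholipid transfer protein, by -0.46 ± 0.10 (adjusted p = 0.0362). Of 8 fits that each left out 1 array, Apoc1 passed in 4 and Mylip and Pltp in 2 (adjusted p up to 0.19). Of 11 further genes of the list measured, 10 had a negative change. The median of the 11, -0.32, lay at percentile 0.05 of 10000 random lists of matched signal. Among the 11 were the genes of the LXR receptors themselves, Nr1h2 (-0.13) and Nr1h3 (-0.11), neither of which passed. The random lists were drawn from unrelated genes, so the percentile takes no account of members that move together between arrays. Lower LXR activity would be 1 possible reading. It was not measured and may share its cause with the fall of the lipid lists.

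Genes of ribosome biogenesis were higher with iodide, among them Mybbp1a, a nucleolar regulator (0.46 ± 0.09, adjusted p = 0.0277), Nhp2, a part of small nucleolar particles (0.43 ± 0.09, adjusted p = 0.0309), and Utp4, of the small-subunit processome (0.43 ± 0.10, adjusted p = 0.0457), each past the threshold in 1 of 8 fits without 1 array (adjusted p up to 0.221). Of 45 further genes measured, 42 had a positive change and 3 passed the threshold. The median of the 45, 0.30, lay at percentile 100 of the random lists. Here too the percentile takes no account of members that move together. Neither this list nor the LXR list was tested with an estimated correlation, by array medians or under other scalings.

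Receptor differences of genes next to each other on the GRCr8 reference correlated at 0.0598 over 10018 pairs, outside the central 95% of 1000 shuffles of gene order (-0.0206 to 0.0193), against 0.0286 for the iodide changes, which also lay outside the central 95% of theirs (-0.0198 to 0.0209), where copy number cannot differ. The most extreme of 8988 windows of 51 genes ran from Il17rc to Pex5, where 44 genes had a negative mean difference in L629F cells (0 past the threshold without and 1, Zfp637, with iodide), with a median of -0.30 (-0.32 without and -0.30 with iodide). In 200 shuffles the 95th percentile of the largest window was 0.18 in size. Copy number was not measured, so a loss of part of a chromosome in the L629F line stayed open.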
